A study of Mus musculus with 6 samples.

How the data were processed

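Lineage-negative, cKit-positive, Sca1-positive cells, a fraction of bone marrow that holds the blood stem cells and the earliest multipotent progenitors, had been sorted from 6-week-old mice carrying 1 GFP reporter allele of Hes1, per the labels. Hes1 is a transcriptional repressor and a target of Notch signalling. The sorted cells were divided into a GFP-positive and a GFP-negative group of 3 arrays each. In each group replicate 1 came from a female and replicates 2 and 3 from males. Total RNA was extracted with a column kit, per the labels' protocols. The same source gives 5 ng as the amount amplified, converted to cDNA and biotin-labelled with the Ovation system for Affymetrix arrays.

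The authors deposited 1 intensity per probe set and array, on a linear scale, for 45101 probe sets. RMA, which corrects background, quantile-normalises the arrays and summarises the probes of a set, is named in the submitters' processing notes, and its version and settings are not given in the sources used here. RMA shrinks differences near background, so fold changes of dim genes are likely to be understated, and quantile normalisation removes any change that affects most genes in 1 direction. The deposited intensities had array medians between 74 and 78.5 and a minimum of 4.12, so log2 was taken with no pseudocount and no further normalisation.

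Probe sets were named from the platform's annotation table: 34958 carried 1 gene symbol, 932 carried several and 9211 were not listed. Of all probe sets 64 were control probe sets, some of them with 1 gene symbol and so kept for the gene test. Of the probe sets with 1 symbol, 34754 matched a mouse RefSeq gene list (GRCm38.p6, used for names only) and 0 symbols changed. Probe sets with several symbols or none were left out of the gene test. For the 9012 genes with several probe sets, the probe set with the highest mean over all 6 arrays stood for the gene, which left 18194 genes with no filter on dim genes. Genomic positions were not used here.

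The groups were compared on the log2 scale with limma 3.58.1 (lmFit and eBayes, in R 4.3.3) without covariates, and p-values were adjusted by Benjamini-Hochberg over the 18194 genes, with a threshold of 0.05. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 26 lists. Beside it stand camera with an estimated correlation and fry, which tests whether a list moves on balance in 1 direction and does not compare it with other genes. The lists covered Notch targets, Notch receptors, ligands and machinery, stem cells, the blood lineages, plasma cells, endothelial and stromal cells, the cell cycle, quiescence, immediate early genes, interferon response, antigen presentation, glycolysis, mitochondrial respiration, ribosome biogenesis, TGF-beta, Wnt and adhesion. A sort gate list and a sex list stayed out of that family. List counts are also given adjusted over the list alone. Single values were compared by a two-sided exact permutation test, in which 3 arrays against 3 cannot go below p = 0.1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

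The groups, tests, gene lists, alternatives and the rule for naming genes were set before the data were examined. The rule named Hes1, genes past the threshold, or, if fewer than 10 passed, the 10 with the smallest p, up to 2 members of smallest p in each list in which none passed, and the sex genes. A gene named outside the rule was chosen after its values were seen, and the text marks it so. Alternatives were the mean of a gene's probe sets, single probe sets, filters at the 40th and 60th percentile of mean level, an intensity trend or robust variance prior, array weights, renewed quantile or median normalisation, the replicate number as a block, sex as a covariate, males alone, other thresholds and the omission of each array in turn.

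The pipeline was tested on simulated data made from the means and spreads of the 18194 genes in this comparison, in 20 runs with 200 changed genes each. It recovered 17.6% of genes simulated at a log2 fold change of 1, 60.3% at 2 and 85.3% at 4, with 7 false calls per run on average. A list shifted by 0.8 was called in 20 of 20 runs by camera at the preset correlation, in 15 with an estimated correlation and in 20 by fry. Genes were simulated as independent, while the correlations estimated for the real lists reached 0.566. The simulation therefore does not show how these tests fare on lists of correlated genes. The number of arrays limits the precision, and the labels do not say that the arrays came from separate animals, so p-values measure only the spread between these samples, which may be technical.

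Xist, expressed from the inactive X chromosome, lay between 12.50 and 12.72 (log2) in the female arrays and between 5.06 and 5.59 in the male arrays. The 3 measured Y-linked genes Uty, Kdm5d and Eif2s3y lay between 6.53 and 10.50 in males and between 3.42 and 4.69 in females, so the arrays matched their sex labels. As transcripts expected to be absent, the Y-linked genes in females give 4.69 as a guide to background and Xist in males gives 5.59, and 3117 and 5310 genes had a mean below these. The 3' minus 5' difference of the Gapdh control probe sets was 0.80 ± 0.16 (SD, n = 3) in GFP-positive and 0.78 ± 0.07 in GFP-negative arrays (two-sided exact permutation p = 0.9), and that of Actb was -0.37 ± 0.04 against -0.39 ± 0.04 (exact permutation p = 0.5). Hybridisation spike controls had mean intensities of 1763 and 1907 on the replicate 1 arrays of the GFP-negative and GFP-positive groups and between 2536 and 2687 on the other 4. No label names a batch, and this split, noticed after the data were seen, coincides with sex. If it marks a hybridisation batch, sex as a covariate also blocks it. Each group holds 1 female and 2 male arrays, so that covariate leaves every fold change as it is and alters only its test.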

Results

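Gene expression was measured on 6 arrays of lineage-negative, cKit-positive, Sca1-positive mouse bone marrow cells, 3 from cells positive and 3 from cells negative for a Hes1-GFP reporter. The comparison asks how early blood progenitors with a GFP signal from the locus of Hes1, a repressor in the Notch pathway, differ from those without it. Values are log2 intensities, and fold changes are GFP-positive minus GFP-negative. Pairwise correlations between arrays over all probe sets lay between 0.925 and 0.951.

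GFP-positive cells had higher levels of stem cell, megakaryocyte, erythroid, B cell, monocyte and macrophage, and cell cycle genes as groups, and lower levels of lymphoid progenitor, interferon response and Notch machinery genes. In all, 13 of the 26 lists passed camera at the preset correlation, 9 higher and 4 lower. With an estimated correlation 0 of the 26 passed (smallest adjusted p = 0.0523), and 8 passed by fry, 1 of which, plasma cell genes, did not pass camera. Cell cycle, interferon response and Notch machinery genes did not pass by fry (adjusted p = 0.103, 0.177 and 0.177), nor did T and NK cell, endothelial and stromal, or immediate early genes (adjusted p = 0.195, 0.394 and 0.699). The calls of these 6 lists rest on camera at the preset correlation alone. The smallest p-values of single genes belonged to Ermap, an erythroid membrane protein, at 4.49 ± 0.30 (log2 fold change ± SE, n = 3 per group), and to the metallothioneins Mt1 and Mt2. These proteins, which bind zinc and copper, were at 2.68 ± 0.21 and 4.30 ± 0.36.

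No single gene passed: by limma, 0 of 18194 genes were higher and 0 lower at an adjusted p under 0.05, and the smallest adjusted p was 0.0956. At an unadjusted p under 0.05, 606 genes were higher and 615 lower, where chance alone gives 909.7 in all. In 1072 genes all 3 GFP-positive arrays lay above the GFP-negative ones and in 1003 all lay below, together 11.4% of genes against 10% by chance. All named genes below therefore carry values that did not pass over all genes, and only lists are called.

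**Figure D1:**
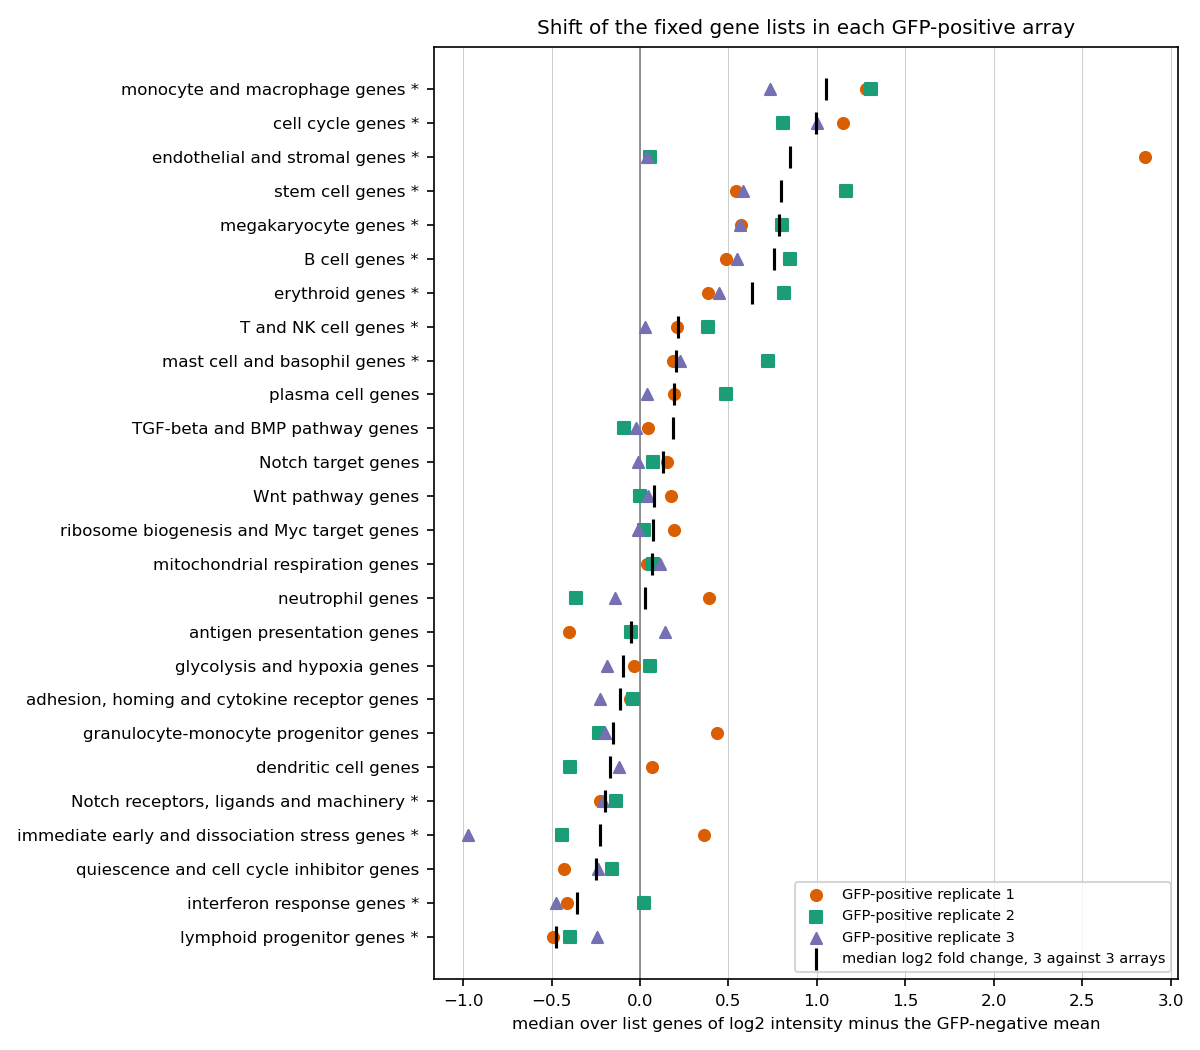
Median over each list's genes of the log2 intensity in each GFP-positive array minus the GFP-negative mean (coloured symbols), with the median log2 fold change over 3 against 3 arrays as a black bar; a star marks lists past an adjusted p of 0.05 by camera at the preset correlation. The endothelial and stromal list lies at 2.85 in GFP-positive replicate 1 and at 0.05 and 0.04 in replicates 2 and 3, while the stem cell list lies at 0.55, 1.17 and 0.59.

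The cells were sorted on GFP from a reporter allele of Hes1, while the arrays measured the Hes1 transcript. Hes1 was at 7.43 ± 0.38 (SD, n = 3) in GFP-positive and 6.89 ± 0.18 in GFP-negative arrays. Its log2 fold change was 0.54 ± 0.24 (SE, limma adjusted p = 0.78). The two-sided exact permutation p was 0.2, where 3 against 3 cannot go below 0.1. GFP-positive replicate 2 lay at 7.09 and GFP-negative replicate 3 at 7.10, so the array signal of Hes1 did not fully separate the groups. Within each replicate number Hes1 was higher in the GFP-positive array: 7.36 against 6.78 for number 1, 7.09 against 6.79 for 2 and 7.84 against 7.10 for 3. In GFP-negative cells it lay above 4.69 and 5.59, a lower and a higher guide to background. The ranking by p, none of which passed, went on with Aldh1a1, a retinaldehyde dehydrogenase, at 3.17 ± 0.28, the monoamine transporter Slc18a1 at -2.76 ± 0.26, the water channel Aqp1 at 2.11 ± 0.21, the transcript C030013G03Rik at -2.06 ± 0.21, the lectin Zg16 at 1.82 ± 0.19, the cytotoxic protease Gzma at 3.17 ± 0.34 and the mast cell chymase Cma1 at 1.96 ± 0.21. Their limma adjusted p-values lay between 0.129 and 0.157. Aldh1a1 and Gzma averaged 4.42 and 4.37 in GFP-negative arrays, below the lower guide to background of 4.69, so their fold changes are likely to be understated. Of the 3 Slc18a1 probe sets, 2 had the same sign, and the probe sets of Mt1 ranged from 0.01 to 2.68 and those of Zg16 from 0.12 to 1.82.

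**Figure D2:**
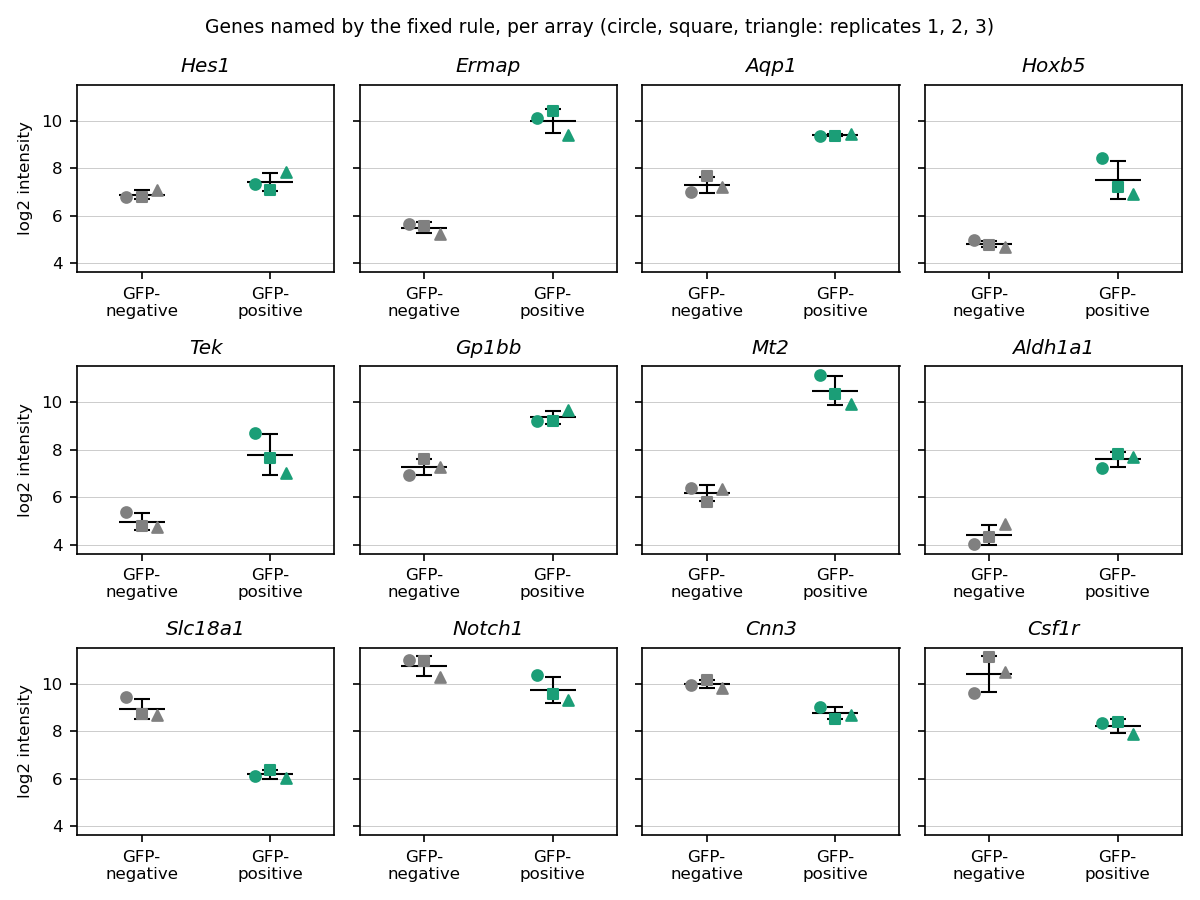
Log2 intensity per array of 12 genes named by the rule; circles, squares and triangles are replicates 1, 2 and 3, and bars give the mean ± SD (n = 3 per group). Ermap lies at 9.99 ± 0.52 in GFP-positive against 5.50 ± 0.23 in GFP-negative arrays, Slc18a1 at 6.19 ± 0.18 against 8.95 ± 0.43, and the Hes1 values of the groups overlap.

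Stem cell genes were higher in GFP-positive cells, with a median of 0.80 over 36 measured genes (camera adjusted p = 2.08e-11; adjusted p = 0.0572 with an estimated correlation). Of these genes 31 had a positive fold change. By limma 0 passed over all genes, 8 adjusted over the list alone, and 14 had an unadjusted p under 0.05. Hoxb5, a homeobox gene of long-term stem cells, was at 7.51 ± 0.80 (SD, n = 3) against 4.81 ± 0.14, and Tek, the angiopoietin receptor of stem and endothelial cells, at 7.80 ± 0.84 against 4.98 ± 0.36. Vwf, a clotting factor made by platelet-biased stem cells and endothelium, was at 2.75 ± 0.61 (log2 fold change ± SE). Procr, a stem cell surface receptor, was at 0.77 ± 0.26, and both were chosen after their values were seen. Not all members rose: Hlf was at -0.05 ± 0.23, Meis1 at 0.002 ± 0.27 and Hoxa9 at -0.48 ± 0.23, chosen in the same way. Endothelial genes stood high in GFP-positive replicate 1, and without that array the stem cell list had a median of 1.00 (camera adjusted p = 7.08e-13; adjusted p = 0.145 with an estimated correlation). Within the replicate 1 pair the median was 0.63 and within the 4 male arrays 0.86.

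Megakaryocyte and erythroid genes were higher. The megakaryocyte list shares Vwf, Trpc6 and Mmrn1 with the stem cell list, at log2 fold changes of 2.75, 2.67 and 1.59, so the 2 lists are not independent. Megakaryocyte genes had a median of 0.78 over 26 genes (camera adjusted p = 1.33e-09; adjusted p = 0.0523 with an estimated correlation). By limma 0 of them passed over all genes and 9 were higher adjusted over the list alone, with 11 higher and 1 lower at an unadjusted p under 0.05. Gp1bb, part of the platelet receptor for von Willebrand factor, was at 9.37 ± 0.27 (SD, n = 3) against 7.27 ± 0.33, and Cavin2, a caveolar protein of platelets, at 9.30 ± 0.61 against 6.69 ± 0.69, with probe sets from 1.29 to 2.61 (log2 fold change). Erythroid genes had a median of 0.63 over 31 genes (camera adjusted p = 1.54e-08; adjusted p = 0.0572 with an estimated correlation). Here limma called 0 over all genes and 7 adjusted over the list alone, and 13 had an unadjusted p under 0.05. Ermap led them, followed by Aqp1 at 9.40 ± 0.05 against 7.29 ± 0.34. Klf1, a master regulator of red cell genes, was at 3.00 ± 0.46 (log2 fold change ± SE) and the carbonic anhydrase Car1 at 2.95 ± 0.36. Both were chosen after their values were seen. Not all erythroid members rose: Fech was at 0.004 ± 0.43, Car2 at 0.05 ± 0.17 and Epb42 at -0.21 ± 0.18, chosen in the same way. Without GFP-positive replicate 1, where endothelial genes stood high, the medians were 0.78 and 0.66. Within the replicate 1 pair and the 4 male arrays they were 0.49 and 0.70 for megakaryocyte genes, and 0.37 and 0.63 for erythroid genes.

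Lymphoid progenitor genes were lower, with a median of -0.47 over 27 genes (camera adjusted p = 0.00039; adjusted p = 0.0572 with an estimated correlation). Over all genes 0 passed by limma, against 1 higher and 1 lower adjusted over the list alone and 1 higher and 8 lower at an unadjusted p under 0.05. The lower one was Cnn3, a calponin, at 8.76 ± 0.26 (SD, n = 3) against 9.99 ± 0.17, with 6 probe sets from -2.99 to -0.33 (log2 fold change). The higher one went against the list: Rag1, which cuts antigen receptor genes, was at 8.42 ± 0.76 against 5.33 ± 0.25. Satb1, a chromatin organiser of lymphoid priming, was at -0.90 ± 0.23 (log2 fold change ± SE) and Flt3, a cytokine receptor of multipotent progenitors, at -0.89 ± 0.38, both chosen after their values were seen. Of the 27 genes 7 had a positive fold change. Besides Rag1 these included Ikzf3 at 2.28 ± 0.98, Il7r at 1.78 ± 0.95 and Ighm at 1.55 ± 0.72, chosen in the same way. Without GFP-positive replicate 1, where endothelial genes stood high, the list median was -0.28 (camera adjusted p = 0.00368; adjusted p = 0.254 with an estimated correlation), and it was -0.50 within the replicate 1 pair and -0.44 within the 4 male arrays.

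B cell genes were higher, with a median of 0.76 over 20 genes (camera adjusted p = 7.28e-06; adjusted p = 0.0572 with an estimated correlation). The limma count was 0 over all genes, 4 adjusted over the list alone and 5 at an unadjusted p under 0.05. Ebf1, a factor of B lineage commitment, was at 7.42 ± 0.45 (SD, n = 3) against 5.17 ± 0.21, with probe sets from 0.70 to 2.24 (log2 fold change), and Pou2af1, a coactivator of immunoglobulin genes, at 8.09 ± 1.36 against 3.27 ± 0.17. Pou2af1 was at 9.7 in GFP-positive replicate 3 and at 7.3 in replicates 1 and 2. The median was 0.76 without GFP-positive replicate 1, 0.56 within the replicate 1 pair and 0.80 within the 4 male arrays. With a filter at the 60th percentile of mean level the camera adjusted p became 0.208. Plasma cell genes did not pass (median 0.20 over 11 genes; camera adjusted p = 0.11), although fry gave an adjusted p of 0.00801 and 2 of 18 alternatives gave a call (lowest adjusted p 0.0317). Jchain, which links secreted antibodies, was at 9.97 and 9.95 in GFP-positive replicates 1 and 2, at 3.50 in replicate 3 and at 3.72 ± 0.14 (SD, n = 3) in GFP-negative arrays. Edem1, of protein quality control in the endoplasmic reticulum, was at 9.64 ± 0.19 against 8.72 ± 0.32.

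Monocyte and macrophage genes were higher, with a median of 1.05 over 23 genes (camera adjusted p = 5.09e-07; adjusted p = 0.0572 with an estimated correlation). Adjusted over the list alone, 7 were higher and 1 lower by limma, against 0 over all genes and 10 higher and 2 lower at an unadjusted p under 0.05. Cd5l, a secreted macrophage protein, was at 9.17 ± 0.29 (SD, n = 3) against 6.06 ± 0.70, and Hmox1, which breaks down heme, at 9.61 ± 0.61 against 7.09 ± 0.52. Csf1r, the receptor that sustains monocytes and macrophages, lay the other way at 8.22 ± 0.29 against 10.42 ± 0.75, and its 3 probe sets ranged from -2.20 to -0.22. Without GFP-positive replicate 1 the list median was 0.91 (camera adjusted p = 1.99e-05; adjusted p = 0.145 with an estimated correlation), and it was 0.99 within the replicate 1 pair and 1.37 within the 4 male arrays. With genes below the 60th percentile of mean level left out, 5 members stayed and their median was -0.37.

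Endothelial and stromal genes, a list that shares Tek and Tie1 with the stem cell list, were higher by camera (median 0.85 over 23 genes, camera adjusted p = 0.000135, adjusted p = 0.462 with an estimated correlation). By limma 0 of these genes passed over all genes, 1 adjusted over the list alone and 4 at an unadjusted p under 0.05. The median was 2.85 in GFP-positive replicate 1 against 0.05 and 0.04 in replicates 2 and 3, and 18 of the 23 genes were highest in that array. Cxcl12, a stromal chemokine that retains stem cells in marrow, was at 12.5, 9.3 and 8.3 in GFP-positive replicates 1, 2 and 3 against 5.41 ± 0.09 (SD, n = 3). Of its 3 probe sets 2 had the same sign. Without GFP-positive replicate 1 the median was 0.07 (camera adjusted p = 0.0496; adjusted p = 0.262 with an estimated correlation), within the replicate 1 pair 3.04 and within the 4 male arrays 0.04 (camera adjusted p = 0.145). Above the 60th percentile of mean level 3 members stayed, with a median of -0.21.

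**Figure D3:**
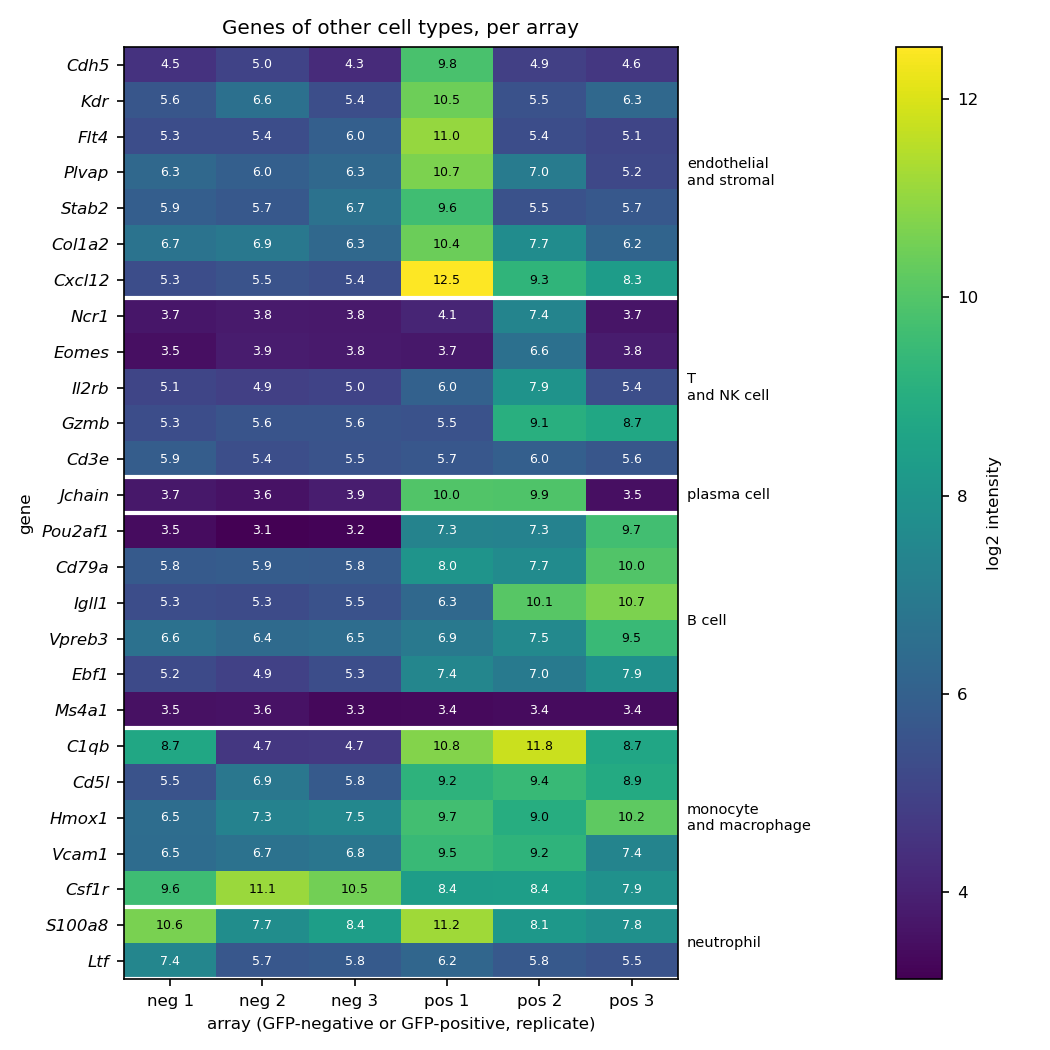
Log2 intensity per array (colour and printed value) of genes of other cell types, chosen from the fixed lists after their values were seen; columns are GFP-negative (neg) and GFP-positive (pos) replicates 1 to 3. Endothelial genes such as Cdh5 are at 9.8 in GFP-positive replicate 1 and at most 5.0 elsewhere, and Ncr1 is at 7.4 in GFP-positive replicate 2 and at most 4.1 elsewhere.

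Cell cycle genes were higher, with a median of 0.995 over 44 genes (camera adjusted p = 1e-15; adjusted p = 0.197 with an estimated correlation). Limma called 0 over all genes and 14 adjusted over the list alone, and 20 had an unadjusted p under 0.05. Aurka, a kinase of the mitotic spindle, was at 10.69 ± 0.19 (SD, n = 3) against 8.06 ± 0.79, while its other probe set had a log2 fold change of 0.04, and Cenpa, the centromeric histone, at 9.96 ± 0.29 against 8.84 ± 0.30, with 2 of its 3 probe sets of the same sign. The median was 0.98 without GFP-positive replicate 1, 0.50 within the replicate 1 pair and 1.23 within the 4 male arrays. Among the GFP-negative arrays replicate 1 stood high, with a median over 24 mitotic genes of 1.00 against -0.38 and -0.49 in replicates 2 and 3. Quiescence genes did not pass (median -0.25 over 24 genes; camera adjusted p = 0.0875; 0.0457 with sex as a covariate, 1 of 4 among 18 alternatives that gave a call). Among them were the cyclin-dependent kinase inhibitor Cdkn2c at 1.23 ± 0.32 (log2 fold change ± SE) and Foxo3, a factor that guards stem cell quiescence, at -0.74 ± 0.20.

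Notch receptors, ligands and machinery were lower, with a median of -0.20 over 30 genes (camera adjusted p = 0.0116; adjusted p = 0.115 with an estimated correlation). Limma called 0 of them over all genes and 0 adjusted over the list alone, with 6 lower at an unadjusted p under 0.05. Notch1, a receptor of the pathway, was at 9.75 ± 0.54 (SD, n = 3) against 10.75 ± 0.41, and Spen, a corepressor, at 7.53 ± 0.65 against 8.79 ± 0.60. The list lost its call in the male arrays alone (median -0.09; camera adjusted p = 0.124) and without GFP-positive replicate 3 (median -0.35; camera adjusted p = 0.0569). Notch targets did not pass (median 0.13 over 16 genes; camera adjusted p = 0.325), and Il2ra, a cytokine receptor chain, was at 4.53 ± 0.35 against 3.96 ± 0.12, close to background.

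Interferon response genes were lower, with a median of -0.36 over 32 genes (camera adjusted p = 0.000135; adjusted p = 0.197 with an estimated correlation). Over all genes and adjusted over the list alone limma called 0, and 5 were lower at an unadjusted p under 0.05. The medians were -0.41, 0.02 and -0.48 in GFP-positive replicates 1, 2 and 3, so replicate 2 was level with the GFP-negative mean. The median was -0.32 without GFP-positive replicate 1. Oas3, an antiviral sensor of double-stranded RNA, was at 7.96 ± 0.23 (SD, n = 3) against 9.37 ± 0.45, and the transcription factor Irf1 at 9.48 ± 0.28 against 10.33 ± 0.28. Immediate early and dissociation stress genes were lower by camera (median -0.23 over 33 genes; camera adjusted p = 0.0425; adjusted p = 0.651 with an estimated correlation), but this call was kept in only 9 of 18 alternatives, lost in 7 and reversed in 2. The medians were 0.36, -0.44 and -0.98 in GFP-positive replicates 1, 2 and 3. Within the replicate 1 pair the median was -0.34 and within the 4 male arrays -0.18 (camera adjusted p = 0.124). The arrays of both groups differed among themselves: Nr4a1, chosen after its values were seen, was at 12.09, 8.57 and 6.28 in GFP-negative replicates 1, 2 and 3 and at 11.20, 7.48 and 5.60 in the GFP-positive ones. By limma 0 members passed over all genes, adjusted over the list alone or at an unadjusted p under 0.05. Ier3 was at -0.87 ± 0.40 (log2 fold change ± SE) and Rhob, a small GTPase, at -0.85 ± 0.37. Without GFP-negative replicate 1 the median was 0.13. Without GFP-positive replicate 1 it was -0.88 (camera adjusted p = 0.000522, adjusted p = 0.507 with an estimated correlation). Either omission leaves a replicate 1 array in only 1 group, so differences between replicate numbers enter these medians. With sex as a covariate the camera adjusted p was 0.00296.

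T and NK cell genes and mast cell and basophil genes were higher by smaller amounts. The T and NK list had a median of 0.21 over 23 genes (camera adjusted p = 0.00341; adjusted p = 0.273 with an estimated correlation). It held 0 genes past the limma threshold over all genes, 1 adjusted over the list alone and 3 at an unadjusted p under 0.05. The 1 was Gzma, at 7.54 ± 0.49 (SD, n = 3) against 4.37 ± 0.44, and the chemokine Ccl5 was at 10.11 ± 0.88 against 8.56 ± 0.15. Without GFP-positive replicate 2 the list median was 0.10 (camera adjusted p = 0.108), and the NK cell gene Ncr1 was high in that array alone. With filters at the 40th and 60th percentile of mean level the T and NK cell genes also lost their call (camera adjusted p = 0.119 and 0.238). The mast cell and basophil list had a median of 0.20 over 17 genes (camera adjusted p = 0.00479; adjusted p = 0.109 with an estimated correlation). The call of the mast cell and basophil genes was also lost above the 60th percentile, where 4 members stayed (median 0.14; camera adjusted p = 0.293). Limma gave 0 over all genes and 1, Cma1, adjusted over the list alone, with 4 higher and 1 lower at an unadjusted p under 0.05. Ms4a2, a chain of the IgE receptor, lay the other way at -1.37 ± 0.44 (log2 fold change ± SE), with 1 of its 2 probe sets of that sign.

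The other lists did not pass. Granulocyte-monocyte progenitor genes had a median of -0.16 and a mean of 0.05 over 27 genes (camera adjusted p = 0.561). Limma gave 4 higher and 1 lower adjusted over the list alone, against 0 over all genes and 4 higher and 2 lower at an unadjusted p under 0.05. The membrane protein Ms4a3, a mark of these progenitors, was at 2.61 ± 0.51 (log2 fold change ± SE), and the neutrophil elastase gene Elane, chosen after its values were seen, at 4.23 ± 0.95. Neutrophil genes had a median of 0.03 and a mean of -0.06 over 16 genes (camera adjusted p = 0.951), with the formyl peptide receptor Fpr2 at 0.42 ± 0.22 and the histone deiminase Padi4 at -0.79 ± 0.47. Dendritic cell genes had a median of -0.17 (camera adjusted p = 0.344), with Ly6d, an early lymphoid surface protein, at 2.35 ± 0.45 and Cd7 at 1.20 ± 0.43. Antigen presentation genes had a median of -0.05 (camera adjusted p = 0.0898; 3 of 18 alternatives gave a call, lowest adjusted p 0.00621), with the class II chaperones H2-Ob at -1.29 ± 0.29 and H2-DMa at -0.77 ± 0.23.

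Pathway lists lay close to 0. Glycolysis and hypoxia genes had a median of -0.10 (camera adjusted p = 0.357), with the hypoxia-induced genes Ankrd37 at 1.61 ± 0.46 (log2 fold change ± SE) and Bnip3 at -0.89 ± 0.25. Mitochondrial respiration genes had a median of 0.07 (camera adjusted p = 0.0635; 6 of 18 alternatives gave a call, with 0.00955 without GFP-positive replicate 1, where adjusted p = 0.262 with an estimated correlation, and 0.00778 in the male arrays alone), with Cox7a2 at 0.33 ± 0.17 and Ndufv1 at 0.32 ± 0.18. Ribosome biogenesis and Myc target genes had one of 0.08 (camera adjusted p = 0.541), with Mycn at 0.64 ± 0.23 and the nucleolar protein Nop56 at 0.33 ± 0.16. TGF-beta and BMP genes had a median of 0.18 (camera adjusted p = 0.57), with Id2, an inhibitor of helix-loop-helix factors, at 2.17 ± 0.33 and the coreceptor Tgfbr3 at 1.32 ± 0.52. Of the 3 Id2 probe sets 2 had the same sign. Wnt genes had a median of 0.08 (camera adjusted p = 0.848), with the pathway's factors Tcf7l2 at -1.32 ± 0.49 and Lef1 at 1.35 ± 0.65. Adhesion, homing and cytokine receptor genes had a median of -0.11 (camera adjusted p = 0.0609; 0.0457 with sex as a covariate, 1 of 5 among 18 alternatives that gave a call), with the sialomucin Cd34 at -0.63 ± 0.17 and the SLAM family member Cd48 at -0.77 ± 0.24. Of the sort gate genes, the leukocyte phosphatase Ptprc was at -0.28 ± 0.16 and Cd4 at -0.65 ± 0.38, each with 1 of 2 probe sets of that sign.

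Probe sets without a single gene name, control probe sets left out, were tested apart. Of 10092 such probe sets, 0 passed by limma over all probe sets and 462 had an unadjusted p under 0.05.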

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

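The tests of sex or batch, of marrow cells of all kinds, of a single array behind the cell cycle genes, and the count of splits for genes past the threshold were chosen only after the result was seen. The female minus male differences were picked out by an interaction test in camera at the preset correlation, and neither passed with an estimated correlation (adjusted p = 0.452 and 0.636). Each group holds 1 female array, so these differences restate single arrays and do not separate sex from them. The tests had 2 residual degrees of freedom, and limma gave 0 genes past an adjusted p of 0.05 for the interaction and 1317 at an unadjusted p under 0.05.

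The endothelial and stromal list shifted by 3.04 in the female pair and by 0.04 in the male arrays, a female minus male difference of 3.000, from medians of 2.85 in GFP-positive replicate 1 and 0.05 and 0.04 in replicates 2 and 3. A second list of 20 endothelial genes, fixed before it was read, lay 2.07 above the other 5 arrays in GFP-positive replicate 1. Of its genes 16 were highest there, against a share of 16.7% if each array were equally likely to be highest. The share of all genes highest in that array was not computed, and genes of such a list may move together. A second stromal list of 13 genes lay 2.69 above the other 5 arrays. A sex or batch effect shared by both replicate 1 arrays would raise the list in GFP-negative replicate 1 too, and it lay at -0.15 there relative to the other GFP-negative arrays, against 1.43 in its GFP-positive partner. Endothelial or stromal cells that passed the sort of that sample are a candidate explanation, with Cdh5 at 9.8 and Kdr at 10.5. How many such cells a lineage, cKit and Sca1 gate lets through was not measured. As this is 1 array, a biological difference of that female sample remains untested, and not all stromal genes were confined to it: Cxcl12 was at 12.52, 9.27 and 8.34 in GFP-positive replicates 1, 2 and 3 against 5.41 ± 0.09 (SD, n = 3), and Bgn and Ibsp, chosen after their values were seen, were at 8.12 and 7.87 and at 7.71 and 6.92 in replicates 2 and 3 against at most 6.11 and 6.57 in GFP-negative arrays.

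Macrophage and B cell genes, which a lineage gate should exclude, were higher in all 3 GFP-positive arrays. Marrow cells of all kinds would bring neutrophil genes too, but the macrophage list exceeded the neutrophil list by 1.14 ± 0.45 (SD, n = 3). The neutrophil medians were uneven, at 0.39, -0.36 and -0.14 in GFP-positive replicates 1, 2 and 3. Some neutrophil genes also varied among GFP-negative arrays, with S100a9 at 11.0, 6.5 and 7.6, while Mmp8 stayed at 4.0 to 4.3. This contrast therefore cannot exclude a small share of marrow cells of all kinds. A second macrophage list had a median fold change of 0.33 (camera adjusted p = 0.0252 over 8 follow-up lists; adjusted p = 0.350 with an estimated correlation) and a second B precursor list one of 0.37 (camera adjusted p = 0.0873; adjusted p = 0.447 with an estimated correlation). Their medians lay between 0.032 and 0.273 and between 0.095 and 0.441 over the GFP-positive arrays, where more than 0.2 in each array had been set as the bound. Single macrophage members, chosen after their values were seen, differed. Fcna, Igf1 and Slc11a1 were at 2.245 ± 0.371, 2.304 ± 0.703 and 1.117 ± 0.284 (log2 fold change ± SE). Siglec1 and Fcgr1 were at -0.011 ± 0.164 and -0.145 ± 0.183. Ctsb was at 11.16 to 11.40 and Ctsd at 11.29 to 11.58 in GFP-negative arrays, so a small share of macrophages may not show in them. So macrophages or early B cells in the sort cannot be told apart from progenitors that express some of these genes, and the high level of Csf1r in GFP-negative cells would hide a small share of macrophages.

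The cell cycle list shifted by 0.50 in the female pair and by 1.23 in the male arrays, a female minus male difference of -0.730. GFP-negative replicate 1 stood apart in it, with a median of 1.00 over 24 mitotic genes against -0.38 and -0.49 in the other GFP-negative arrays. Both groups hold 1 replicate 1 array and 2 male arrays, so an effect of sex or of a batch common to both groups cancels, and the shifts of 0.503 and 1.233 within these sets restate the pattern and test no cause. Other cells in GFP-positive replicate 1 as the whole cause are argued against by a median of 0.982 without that array, against 0.995 with it. A larger share of dividing cells among GFP-positive progenitors is a hypothesis that stays open beside dividing cells of other types and an effect of sex or batch that differs between the groups.

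The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Genes past an adjusted p of 0.05 numbered 0 in the real split and 0 at most in the others, so all 10 gave as many. Genes at an unadjusted p under 0.05 numbered 1221 in the real split and at most 969 in the others, and lists passing numbered 13 against at most 10, so 1 of the 10 splits, the real one, gave as many in each case.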

How the results depend on the processing

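All alternatives here were planned. Hes1 lay between 0.33 and 0.71 in all 17 alternatives and passed in none. Genes higher past the threshold numbered 0, and 1 with genes below the 40th percentile of mean level left out (Ermap, adjusted p = 0.047), 2 at the 60th percentile (Mt1 and Mt2, adjusted p = 0.048), both with fewer genes tested, and 1 at an adjusted p under 0.1. Leaving out single arrays gave 0 to 5, the 5 being Ermap, Pou2af1, Jchain, Igk and Igkv8-30 without GFP-positive replicate 3. Lists passing numbered 13, and 0 with an estimated correlation and 8 by fry, against 9 to 15 otherwise (14 without GFP-positive replicate 1, 15 with sex as a covariate, 12 in males alone). Deviations from the group mean correlated at 0.124, 0.0503 and 0.0922 between same-numbered arrays, against -0.0983 to 0.00774 between arrays of unlike number. Each array thus correlated best with its own number. The correlations were small and the labels do not say whether the numbers pair the arrays, so a pairing that the main test leaves out remains possible. With the replicate number as a block, 0 genes passed (1390 at an unadjusted p under 0.05; smallest adjusted p 0.352), 14 lists passed and Hes1 was at 0.54.

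Over all alternatives, list shifts kept direction and side in 401 cases, lost the call in 27, gained a call in 20 and reversed in 20. For single genes these counts were 947, 0, 6 and 1. No named gene passed in the main test, so none could lose a call, and keeping its side means only not passing again. Sex as a covariate, the replicate block and another variance prior cannot alter a gene's fold change. The reversals, whose cause was not tested except where few members stayed, were Ptprc at 0.180 by the mean of its probe sets and Wnt genes at -0.013 above the 40th percentile. Above the 60th percentile they were Notch targets at -0.602 (2 members), macrophage genes at -0.374 (5 members), endothelial genes at -0.207 (3 members), TGF-beta genes at -0.343 and Wnt genes at -0.270. With array weights, which gave GFP-positive replicate 1 the lowest weight of 0.545, neutrophil genes were at -0.221 and antigen presentation genes at 0.007, and in males alone neutrophil genes were at -0.083 and TGF-beta genes at -0.006. Leaving out single arrays moved immediate early genes between -0.875 and 0.127, neutrophil genes between -0.482 and 0.199, ribosome biogenesis genes between -0.025 and 0.103, Wnt genes between -0.053 and 0.082, antigen presentation genes between -0.182 and 0.006, TGF-beta genes between -0.101 and 0.262 and glycolysis genes between -0.100 and 0.007. Signal over background limits the dim genes, whose changes RMA compresses.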

Other observations

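The split of cell cycle genes by phase, the test of the heme list and its repeat without 2 genes were chosen only after the result was seen, and so were the genes named here. Igk, an immunoglobulin light chain, was at 13.27 and 12.69 in GFP-positive replicates 1 and 2 and at 5.15 in replicate 3, against 4.67 ± 0.32 (SD, n = 3) in GFP-negative arrays, and Jchain was at 9.97, 9.95 and 3.50 in the same 3 arrays. Ighm, of the B cell and lymphoid progenitor lists, was at 12.35, 12.21 and 9.80 in GFP-positive replicates 1, 2 and 3. In GFP-negative arrays Ighm was at 9.37 to 10.20. Not all plasma cell genes followed in replicates 1 and 2: Tnfrsf17 was at 5.98 and 5.64 against 5.78 ± 0.04, Prdm1 at 5.40 and 5.50 against 5.56 ± 0.09, and Sdc1 at 7.45 and 5.70 against 8.24 ± 0.74. The NK cell receptor Ncr1 was at 7.38 and the NK cell factor Eomes at 6.58 in GFP-positive replicate 2, against 4.08 and 3.74 in replicate 1 and 3.67 and 3.84 in replicate 3. Klrd1 and Il2rb were at 8.48 and 7.95 in replicate 2, against 4.28 and 6.04 in replicate 1 and 5.33 and 5.40 in replicate 3. In GFP-negative arrays Klrd1 reached 7.08. Not all NK cell genes followed in replicate 2, with Prf1 at 8.68 against 8.98 ± 0.80 and Nkg7 at 11.24 against 11.23 ± 0.03 in GFP-negative arrays. These levels in GFP-negative arrays were high, so a small share of NK cells may not show in Prf1 and Nkg7. In replicate 3 the B precursor genes Cd79a, Igll1 and Vpreb3 were at 9.98, 10.67 and 9.48, against 5.83, 5.38 and 6.50 on average in GFP-negative arrays. In GFP-positive replicate 1 they were at 7.99, 6.32 and 6.92 and in replicate 2 at 7.67, 10.10 and 7.54. The mature B cell gene Ms4a1 was at 3.4 in all 3 GFP-positive arrays.

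Within the cell cycle list, the median of 24 genes of mitosis exceeded that of 20 genes of DNA replication by 1.07 to 1.77 in the 3 GFP-positive arrays, by 0.75 in GFP-negative replicate 1 and by -0.18 and -0.45 in GFP-negative replicates 2 and 3. Mcm6, a subunit of the replicative helicase, was at 12.65 ± 0.16 (SD, n = 3) against 12.70 ± 0.10, while Ube2c, which drives mitotic exit, was at 12.81 ± 0.37 against 10.09 ± 1.78. Not all replication genes were level: Tk1 had a log2 fold change of 0.95, Rrm2 of 1.04 and Ccne1 of 1.18. The smallest difference, 1.073, was computed on the genes that showed the pattern, so it restates the pattern and tests no explanation of it.

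Mt1 and Mt2 raised the hypothesis of a metal response, for which a list of 8 other metal-response genes was fixed before it was read. Its median was -0.042 (camera adjusted p = 0.323 over 8 follow-up lists), below the bound of 0 set against the hypothesis. The GFP-positive arrays lay on both sides of 0, at -0.21, -0.09 and 0.02. Its member Slc30a1 was lower in every GFP-positive array (8.1 to 8.4) than in any GFP-negative one (8.5 to 8.9). Of all genes 11.4% separated the groups in this way, in either direction, against 10% by chance. Slc30a1 was at -0.53 ± 0.19 and Mtf1 at -0.85 ± 0.59 (log2 fold change ± SE). The Mtf1 value came mainly from GFP-positive replicate 1, at 6.07 against 8.05 and 8.22 in replicates 2 and 3. Slc30a10, Mt4 and Selenow were also below 0, while Slc39a10, Mt3 and Ndrg1 were above it at 0.21, 0.10 and 0.05. Slc30a1 is 1 gene, and the list holds genes that may not respond in these cells, so the list decides little. An oxidative stress list of 8 measured genes had a median of 0.090 (camera adjusted p = 0.638). Hmox1 raised the hypothesis of a heme and iron program, and a list of 9 measured genes had a median of 0.327 (camera adjusted p = 0.0814 over those lists). Before adjustment it passed the bound of 0.05 that had been set for it (camera p = 0.0407 at the preset correlation). With an estimated correlation it did not (camera p = 0.169, adjusted p = 0.452). Slc40a1, which exports iron, and Blvrb, which reduces biliverdin, had been seen to be higher before that list was written, and without them the median was 0.011 (camera adjusted p = 0.496), so the list gives no evidence beyond those genes.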
